A study of Homo sapiens with 5 samples.

How the data were processed

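RNA from SK-NL-SETDB1 melanoma cells was labelled with biotin and hybridised to Illumina arrays, per the labels. The authors deposited a table of raw probe signals, linear intensity with no background subtracted, per the file headers and from the values. Beside each signal the deposited table gives a detection p-value; nearly all of these differ from one another, so they are not ranks among control probes, and how they were computed was not given in the sources used here. The authors also deposited a value table on the log2 scale, quantile normalised from its values, each column with a median of 6.71. Its background correction and centring stay unknown.

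The 2 tables do not hold the same 5 arrays. Over all probes, 4 columns of the raw table had a Spearman correlation of at least 0.9999 with a column of the authors' table. Replicates 2 and 3 of overexpression in the raw table were replicates 1 and 2 in the authors' table. Overexpression replicate 1 of the raw table and replicate 3 of the authors' table matched no column, with 0.793 as the highest correlation. There were thus 6 distinct arrays, and replicate numbers here follow the raw table, on which all tests were run. Where all 6 were set together on the authors' scale, overexpression replicate 1 was given that table's quantiles by the rank of its raw signals. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

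Of the probes 48104 were used and 3 were left out for a missing value. The platform annotation gave 1 gene symbol for 30113 probes, several for 8 and none for 17983, and 30074 of the named probes had an identifier in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. Signals were corrected with limma's nec on the detection p-values, with an offset of 16, then quantile normalised and put on the log2 scale. To estimate the background, nec reads these p-values as ranks among control probes, which they are not here. The background estimate is therefore uncertain. Control probes were not separated from the others. A probe was tested if its detection p was under 0.05 on at least 2 arrays, which left 23861 probes. The brightest probe stood for a gene, which gave 19423 features, 6730 of them probes with no name. In 1277 of 3432 genes with several tested probes the probes disagreed in sign. Where no array of a group had a detected signal, a bound is given. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. The bound holds only for this background correction and these arrays. It equals the plain ratio where the probe's own signal is the higher on every array of the dim group.

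Groups were compared with lmFit and eBayes (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. With an estimated correlation camera rests on only 3 residual degrees of freedom, so a list can fail it for want of power. Chip was entered as a block, which equals leaving out empty vector replicate 2. The genes named are SETDB1, THBS1, and, since none passed, the 6 of smallest p per direction and the 2 of smallest p per list. Unnamed, provisional and Y-linked symbols were not eligible. These rules, the 26 lists and the alternatives were fixed before the data were examined. Alternatives varied the background correction, normalisation, offset, filter, choice of probe, chip and replicate blocks, variance model, array weights, threshold and list test, used the authors' table, and left out each array in turn. The alternatives with all 6 arrays, or with the authors' table without its unmatched array, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

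The gene test was tested on simulated data of 19423 features and the same numbers of arrays, in 20 simulations with 200 changed genes each. It recovered 14.3% of genes changed 2-fold and 95.8% of those changed 4-fold, with 8.65 false calls per simulation. A list shifted by 0.4 was recovered in 20 of 20 simulations of independent genes, and 3 lists were called in simulations with no shift. These simulations hold no correlation between genes and no chip effect. Their SDs per gene were those already moderated by eBayes, and 200 changed genes ease the adjusted threshold. The shares recovered therefore do not show that 4-fold changes were absent from the real arrays. There CHST9 differed by -2.29 on the log2 scale with a limma adjusted p of 0.740.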

Results

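Transcript levels were measured on Illumina HT-12 v4 expression arrays in SK-NL-SETDB1 cells, a subclone of the human melanoma line SK-MEL-28 with a normal SETDB1 copy number per the labels. SETDB1 is a methyltransferase that places repressive marks on lysine 9 of histone H3. The deposited table of raw signals held 2 arrays of cells carrying an empty vector and 3 arrays of cells overexpressing SETDB1. By the labels, empty vector replicate 2 lay alone on chip 2 and the other 4 arrays lay on chip 1. Between 45.2% and 46.1% of probes were detected per array, and the median raw signal lay between 109 and 122. After the filter on dim probes 19423 features were tested, of which 12693 had a gene name. The small number of arrays limits the precision of every value.

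The first question was whether the SETDB1 signal differed between the groups. The single SETDB1 probe read 8.12 ± 0.60 (SD, n = 2) on the log2 scale in the empty vector arrays and 7.66 ± 0.15 (SD, n = 3) in the overexpression arrays. The difference was -0.46 with a standard error of 0.30, limma adjusted p = 0.762, so the signal was not higher in the cells labelled as overexpressing. The controls read 7.69 and 8.54, and the overexpression arrays 7.58, 7.57 and 7.83. Within chip 1, where only empty vector replicate 1 remained as a control, the difference was -0.03. Which part of the transcript the construct carries was not given in the sources used here, so this probe does not settle how much SETDB1 was made. THBS1, which encodes the matrix protein thrombospondin 1, was not well above background in either control and was detected on 2 of 3 overexpression arrays. With the background correction used its signal was higher by at least 1.32-fold and did not pass correction (limma adjusted p = 0.740). Without overexpression replicate 1 this bound fell to 1.24-fold.

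**Figure D1:**
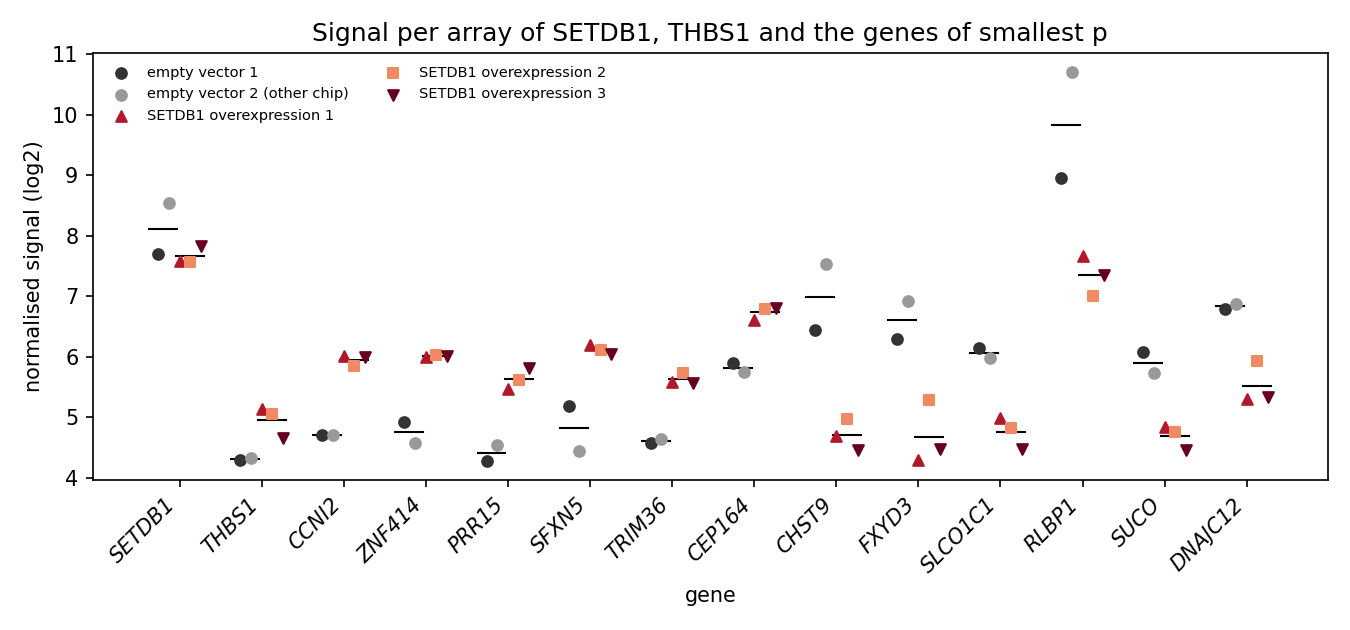
Normalised log2 signal (vertical axis) of SETDB1, THBS1 and the 6 genes of smallest p in each direction, for each of the 5 arrays, with a line at each group's mean. SETDB1 averaged 8.12 in the empty vector arrays and 7.66 in the overexpression arrays.

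The second question was which genes differed between SETDB1 overexpression and the empty vector. The gene of smallest p among those higher with overexpression was CCNI2, a cyclin family member (2.37-fold, not well above background in the controls). Both controls read above the lowest detected signal for CCNI2, so this is the plain ratio and not a lower bound. Next were ZNF414 (1.26 on the log2 scale), PRR15 (at least 2.13-fold) and SFXN5, a mitochondrial carrier (1.31). TRIM36 (1.02) and CEP164, a centriole protein (0.92), came last. Among those lower were the sulfotransferase CHST9 (-2.29), the ion transport regulator FXYD3 (-1.92) and the thyroid hormone transporter SLCO1C1 (-1.30). The retinoid-binding protein RLBP1 (-2.48, or -1.60 within chip 1), SUCO (-1.22) and the chaperone DNAJC12 (-1.32) were lower too. CHST9, FXYD3 and SUCO were detected on only 1 of 3 overexpression arrays. ZNF414, SFXN5 and TRIM36 were detected on only 1 of 2 controls. The dimmer side of these 6 differences thus lies partly at background. Other tested probes read 0.40 for CCNI2, 0.10 and -0.19 for TRIM36 and -0.16 for SUCO, while those of FXYD3 and DNAJC12 were lower too. None of the values given for these 12 genes passed correction, each with a limma adjusted p of 0.740. Their sizes, and with them the bounds, hold only for the background correction used. Without it 11 of the 12 moved by over 1.5 times, with CCNI2 at 0.40, CHST9 at -0.95, FXYD3 at -0.77 and SLCO1C1 at -0.44, and so did 11 with the authors' table, with TRIM36 at 0.055. Of all 61 genes named here besides SETDB1, 36 moved as far or turned without background correction and 49 with the authors' table. Leaving out empty vector replicate 1 or 2 moved 15 and 26 of them, and leaving out overexpression replicate 1, 2 or 3 moved 8, 9 and 1. With limma 0 genes were higher and 0 lower at an adjusted p under 0.05, while 1270 features had an unadjusted p under 0.05 (558 higher, 712 lower) against 971 expected by chance. The 3 overexpression arrays lay apart from both controls in 22.9% of features, where chance gives 20%. Within chip 1 the smallest adjusted p was 1 and 618 features had an unadjusted p under 0.05.

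The third question was whether genes of lists fixed before the data were examined shifted together. Of 26 lists 23 had at least 5 tested genes, and 6 passed camera, which asks whether a list's genes shift relative to all other genes. Of the genes of melanocyte differentiation and pigmentation, 24 of 29 were lower with overexpression (median -0.39, camera adjusted p = 0.000124, but adjusted p = 0.706 with an estimated correlation). They included the pigment enzyme TYRP1 (-2.91 with a standard error of 0.92, or -1.58 within chip 1) and APOE (-1.07 with a standard error of 0.28). The list's median, taken against the mean of both controls, was -0.38, -0.49 and -0.14 on the 3 overexpression arrays and -0.18 and 0.18 on the controls, so overexpression replicate 3 lay between the controls. Cholesterol synthesis genes were lower in 18 of 19 cases (median -0.35, camera adjusted p = 0.00169, but adjusted p = 0.706 with an estimated correlation), among them IDI1 (-0.93, or -0.60 within chip 1) and INSIG1 (-0.62, or -0.41). Interferon-stimulated genes were lower in 24 of 37 cases (median -0.10, camera adjusted p = 0.0379, but adjusted p = 0.706 with an estimated correlation), with BST2 (-1.98) and the chemokine CXCL10 (-1.43, or -0.63 within chip 1) as the members of smallest p. Overexpression replicate 3 lay between the controls in the other 2 lists as well. Without empty vector replicate 2 the camera adjusted p was 0.124 for pigmentation, 0.331 for cholesterol synthesis and 0.192 for interferon-stimulated genes. Cholesterol synthesis also failed without overexpression replicate 2 (adjusted p = 0.0526) and with the authors' table (median -0.12, adjusted p = 0.0933). Interferon-stimulated genes failed without empty vector replicate 1 (0.0923) or overexpression replicate 1 (0.119) or 2 (0.121), with no filter on dim probes (0.233) and with array weights (0.0761). Without empty vector replicate 1 the 3 medians were -0.60, -0.60 and -0.19, without empty vector replicate 2 that of cholesterol synthesis was -0.12, and without overexpression replicate 3 that of interferon-stimulated genes was -0.20.

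Clustered protocadherins, neuronal adhesion genes, were higher in 14 of 16 cases (median 0.39, camera adjusted p = 0.00902, but adjusted p = 0.706 with an estimated correlation). This list's estimated correlation was -0.0205, under the preset 0.01, yet its unadjusted camera p rose from 0.00118 to 0.0401. Failing that form of camera thus does not show that correlation between genes made the call, and decides nothing about it. PCDHGA7 (at least 1.68-fold) and PCDHA11 (at least 1.32-fold) were not well above background in the controls. Only 16 of the 57 listed members were tested, and some passed the filter through the overexpression arrays alone. With no filter the median was 0.13 and the list did not pass (adjusted p = 0.205), nor did it without background correction (0.0752), with a larger offset (0.056) or with the authors' table (0.128). Genes of the TGF-beta response were higher in 13 of 16 cases (median 0.22, camera adjusted p = 0.0276, but adjusted p = 0.706 with an estimated correlation), among them LTBP3 (0.91), which binds latent TGF-beta, and the transcriptional inhibitor ID2 (1.12, but 0.38 within chip 1). This list's median against the control mean was -0.03 on overexpression replicate 3, between the controls at 0.19 and -0.19, and the list median was 0.60 without empty vector replicate 1. Genes of the dedifferentiated or invasive melanoma state were higher in 13 of 17 cases (median 0.35, camera adjusted p = 0.0388, but adjusted p = 0.706 with an estimated correlation), among them the collagenase MMP1 (0.95) and CCN1 (0.69). The call for this list was lost under most changes of processing, with an adjusted p from 0.0506 with no filter to 0.274 with strict detection. Without empty vector replicate 2 the camera adjusted p was 0.124, 0.415 and 0.0875 for the protocadherin, TGF-beta and dedifferentiated lists. There the protocadherin median was 0.23. The TGF-beta list also failed without overexpression replicate 1 (0.0797) or 2 (0.135) and with the authors' table (0.177), and the dedifferentiated list without empty vector replicate 1 (0.255) or overexpression replicate 1 (0.0797) or 2 (0.236). The test fry, which asks whether a list's genes move on balance one way, passed 0 of the 23 lists (smallest adjusted p = 0.453), and its mixed form, for change in either direction, also passed 0 (0.290). Within chip 1 the medians of the 6 lists kept their direction, from -0.20 for pigmentation to 0.30 for the dedifferentiated state, and 0 lists passed (smallest camera adjusted p = 0.0875).

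**Figure D2:**
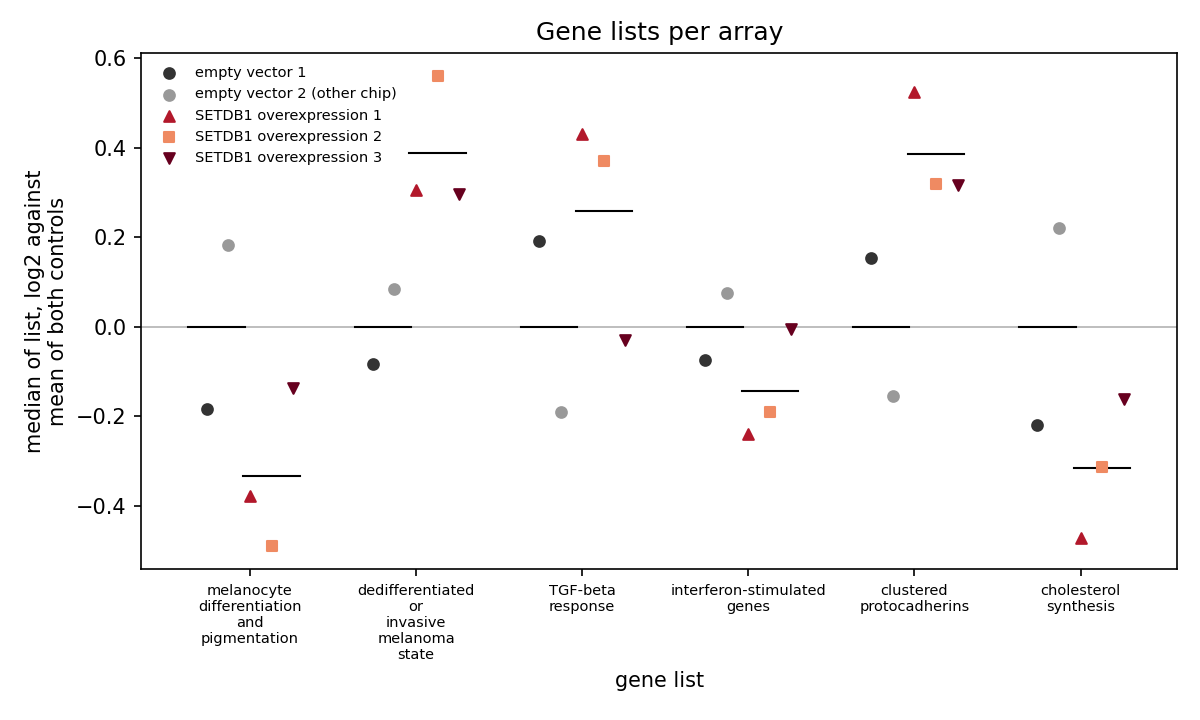
Median over each list's genes of the log2 signal against the mean of both controls (vertical axis) on each of the 5 arrays, for the 6 lists that passed camera, with lines at the mean of each group's array medians. For pigmentation the overexpression arrays sit at -0.38, -0.49 and -0.14 and the controls at -0.18 and 0.18.

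The other tested lists did not pass camera. Partners of SETDB1 and of H3K9 methylation were higher in 13 of 22 cases (median 0.09, mean -0.01, adjusted p = 0.891), with the DNA methyltransferase DNMT3B (-0.82) and the heterochromatin protein CBX5 (-0.90, or -0.42 within chip 1) as the members of smallest p. Among extracellular matrix and adhesion genes 18 of 29 were lower (median -0.13, adjusted p = 0.515), among them LUM (-1.98, or -1.09 within chip 1). Output genes of the BRAF-MEK-ERK pathway were lower in 11 of 20 cases (median -0.10, adjusted p = 0.676), with DUSP4 at 0.75 (0.03 for its other tested probe) and SPRED2 at 0.89 (0.49 within chip 1). Cell cycle genes were higher in 30 of 44 cases (median 0.09, adjusted p = 0.498), with CCNE1 at 0.49 and BIRC5 at 0.57, or 0.09 and -0.0045 within chip 1. Without overexpression replicate 1 BIRC5 was at 0.29 and without replicate 2 at 0.97. Single arrays decided this list. Without overexpression replicate 2 it passed as higher at the preset correlation (median 0.42, adjusted p = 2.52e-05, but adjusted p = 0.766 with an estimated correlation), as it did without empty vector replicate 1 (0.36, adjusted p = 0.0114, but adjusted p = 0.715 with an estimated correlation). Without empty vector replicate 2 its median was -0.18 (adjusted p = 0.178) and without overexpression replicate 1 it was -0.11 (adjusted p = 0.509). Targets of p53 had a median of 0.06 and a mean of -0.03 (adjusted p = 0.993), with CCNG1 at -0.54 (-0.21 within chip 1) and GDF15 at -0.90. Without overexpression replicate 1 these were -0.84 and -0.44, and without replicate 2 -0.26 and -1.59, while without empty vector replicate 1 GDF15 was at -0.53. Antigen presentation genes had a median of -0.06 (adjusted p = 0.774), with HLA-DQB1 at -1.02 (-0.68 within chip 1) and HLA-DRA at 0.54 (0.32 without overexpression replicate 1, and 0.25 for its other probe). Inflammatory cytokine and NF-kB genes had a median of -0.18 (adjusted p = 0.891), with IL1B at 1.66 (0.99 without overexpression replicate 2) and NFKBIA at -0.71 (-0.14 within chip 1). The median was -0.68 without empty vector replicate 1, 0.21 without empty vector replicate 2 and 0.14 without overexpression replicate 1. Germline and cancer-testis genes had a median of -0.11 (adjusted p = 0.336), with MAGEA10 at 1.66 and TAF7L at -1.22, or 1.04 and -0.72 within chip 1.

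Zinc finger genes were lower in 180 of 349 cases (median -0.03, adjusted p = 0.521), with ZNF414 at 1.26 and ZNF821 at -0.96. HOX and developmental regulators had a median of 0.12 (adjusted p = 0.206), with DLX5 at 1.14 (0.73 within chip 1) and HOXD13 at 0.47. Hypoxia and glycolysis genes had a median of -0.07 (adjusted p = 0.498), with the glucose transporter SLC2A3 at -0.95 and ANKRD37 at -0.89, each -0.47 within chip 1. Unfolded protein response genes had a median of -0.05 (adjusted p = 0.774), with SDF2L1 at 0.56 and ATF3 at -0.79, or 0.19 and -0.34 within chip 1, and ATF3 at -0.47 without overexpression replicate 1. Heat shock and immediate early genes had a median of 0.10 and a mean of -0.15 (adjusted p = 0.907), with FOS at -1.10. Within chip 1 FOS was at -0.23 and the list median at -0.09. FOS read 9.77 in empty vector replicate 2 and 8.04 in replicate 1. Genes taken as ribosomal by their symbols had a median of -0.02 (adjusted p = 0.716), with RPSA2 at -0.54 (-0.28 within chip 1) and RPS6KA4 at 0.51, which encodes a kinase and not a ribosomal protein. Oxidative phosphorylation genes had a median of -0.01 and a mean of 0.01 (adjusted p = 0.993), with CYCS at 1.25 (0.74 within chip 1) and COX6B2 lower by at least 1.41-fold and not well above background with overexpression. Neural crest and Schwann-like genes had a median of -0.19 (adjusted p = 0.336), with ERBB3 at -0.67 and GFRA1 lower by at least 1.53-fold. The list median turned to 0.10 with the mean of a gene's probes, 0.03 with no filter and 0.02 with every probe apart or strict detection, and the 2 other probes of ERBB3 read higher, at 0.25 and 0.73. Of the 17 tested lists that did not pass, the median turned sign in 12 when 1 array was left out, and in 9 of them within chip 1. In 12 it turned under another choice of processing, block or table, chip as a fixed block not counted. Of the 6 lists that passed 0 turned, but they were picked for their shift on these same arrays. That count therefore lends them no support.

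Markers of other cell types were also measured. Immune cell markers had a median of -0.13 (camera adjusted p = 0.716), with CD68 at -0.61 and LCP1 at -1.49, or -2.32 without overexpression replicate 2, which lay between the controls. Fibroblast markers had 4 tested genes and no list test, with LUM at -1.98 and COL1A1 at -0.25, or -0.98 within chip 1 and 0.48 without empty vector replicate 1. Keratinocyte markers, also with 4, were all higher, with KRT15 at 0.94 and DSG3 by at least 1.14-fold, a bound that is lost without overexpression replicate 2. Of the endothelial markers 2 were tested, ENG at 0.29 (0.17 without overexpression replicate 2) and EGFL7 at 0.11 (-0.16 within chip 1). Adjusted over the list alone, LUM passed among the fibroblast markers (adjusted p = 0.0207) and 0 genes passed in each of the other 25 lists, against 0 genes over all features tested.

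**Figure D3:**
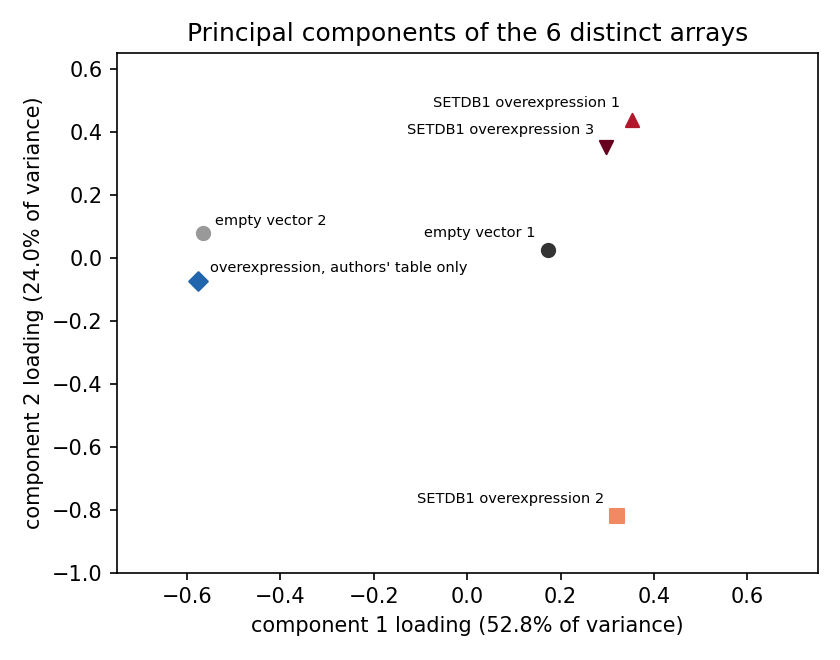
Loadings of the 6 distinct arrays of both deposited tables on the first component (horizontal axis, 52.8% of variance) and the second (vertical axis, 24.0%), over 7365 bright features on the authors' log2 scale. Overexpression replicate 1, absent from the authors' table, was put on this scale by the rank of its raw signals. The overexpression array found only in the authors' table sits beside empty vector replicate 2 on these components, while on the third (13.4% of variance, not drawn) they lie far apart, at -0.697 and 0.667.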

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

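The tests below were chosen after the results were seen, except the counts of lists and of genes over other splits of the arrays. The authors' table holds 1 overexpression array that the comparison did not use. On it THBS1 read 6.57 on the authors' log2 scale, against 6.48 and 6.51 in the controls. Overexpression replicates 1, 2 and 3 read 6.82, 6.80 and 6.68. Replicate 1 is not in the authors' table, so all its values on this scale come from its raw ranks set to the authors' quantiles. THBS1 was not detected in either control or on replicate 3, so a value of 6.57 cannot be told from background. The median of the dedifferentiated or invasive list against the control mean was 0.115 on the unmatched array, above both controls. Against control 2 alone 10 of that list's genes were higher and 7 lower (median 0.03). Against the control mean, interferon-stimulated genes (-0.175) and pigmentation (-0.075) also kept the direction of their calls. Cholesterol synthesis (0.115), TGF-beta (-0.0625) and protocadherins (-0.015) went the other way. Of the cholesterol genes 16 of 19 lay above control 1, and of the TGF-beta genes 12 of 16 lay below it. SETDB1 read 8.44, between the controls at 8.02 and 8.61 and above the other overexpression arrays at 7.94, 7.93 and 8.11. Of the pigmentation genes 26 of 29 lay below control 2 (median -0.27), but 13 lay below control 1 and 16 above it (median 0.03), so the array was level with control 1 in this list.

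That array was nearest to empty vector replicate 2, with a Pearson correlation across genes of 0.978 against 0.946 to 0.962 with the other arrays. The third component put control 2 at 0.667, control 1 at 0.206, overexpression replicates 2, 3 and 1 at 0.0278, -0.0516 and -0.152, and that array at -0.697. This is the order of the labels, but the component was picked after the components were seen. The first 2 left control 2 and that array together, so a later component was bound to part them. The order thus decides nothing about the label of that array. If it were a control array under an overexpression label, its difference from control 2 should not follow the overexpression arrays minus control 1. These correlations across genes were 0.147, 0.169 and 0.0896, where differences between pairs of overexpression arrays gave -0.0428, 0.0755 and 0.0843. The mean of the 3 overexpression arrays minus control 1 gave 0.199, over 2 times the largest reference, and the test first used this value and argued against a wrong label; its rule was changed after that result, since the references are differences of single arrays. By the changed rule the lowest value, 0.0896, was close to the references, so a wrong label stays open, as does a technical factor shared with control 2.

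The SETDB1 signal was not higher with overexpression. A higher reading of control 2 on its own chip may account for the lower mean, since within chip 1 the difference was -0.0342, less than the spread of 0.15 between overexpression arrays. It does not account for the lack of a higher signal. The annotation names 1 SETDB1 probe, so a construct that this probe does not read could not be told apart from a construct with little expression.

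The pigmentation list was lower with overexpression, and not on overexpression replicate 2 alone. Replicate 1 had 23 of 29 genes below control 1 and 25 below control 2, though replicate 3 had 12 below control 1. Without replicate 2 the list passed camera at the preset correlation (adjusted p = 0.00901) with a median of -0.263, just past the bound set. That pass carries little weight, since its rule was written after the result and other splits of the arrays passed too. The rule for this test was tightened after its result was seen, to ask also for a pass with an estimated correlation (adjusted p = 0.766), and then set back, since with all 5 arrays the list fails that as well (adjusted p = 0.706). Within chip 1 the median was -0.198, but overexpression replicate 3 lay 0.0876 above control 1, so the chip of control 2 stays open. The 10 splits of the 5 arrays into 2 and 3 are too few for a share under 0.05. Of them 3, the real split included, gave as small a camera adjusted p. It was 0.000124 for the real split and 4.96e-07 as the smallest of the others. A biological effect of SETDB1 remains untested.

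Over the same splits, 2, the real split included, gave as many lists past the threshold, with 6 for the real split and 6 as the highest of the others. For features with an unadjusted p under 0.05, 3 splits, the real one included, gave as many. There were 1270 for the real split and 1626 as the highest of the others. The split of overexpression replicates 1 and 3 from the rest called 9 genes at an adjusted p under 0.05, where the real split and all others called 0. It was picked out after all splits were seen, and the cause of its calls was not tested.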

How the results depend on the processing

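The counts of 0 genes higher and 0 lower held under every alternative run, and SETDB1 stayed below the control mean in all of them, from -0.89 to -0.03 as each array was left out. Of the 6 lists past camera, 2 still passed with the authors' table, where 3 passed and oxidative phosphorylation was the other, 3 with no filter on dim probes, and 0 with chip as a block, an estimated correlation or fry. Leaving out each array gave 0 to 6 lists. Of the 6, 0 still passed without empty vector replicate 2, 4 without empty vector replicate 1, 3 without overexpression replicate 1 and 2 without overexpression replicate 2, and cell cycle was a further list without empty vector replicate 1 or overexpression replicate 2 and with array weights. The cause was not tested, except that the chip block and leaving out control 2 are one and the same fit on fewer arrays. Chosen after seeing the data, all 6 distinct arrays gave 6 lists, of which 4 were among the first 6 and the others were HOX regulators and hypoxia, and the authors' table without its unmatched array gave 2. EGFL7 reversed to -0.0077 with the mean of its probes, -0.12 with every probe apart, -0.16 with chip as a block, -0.043 with the replicate block and -0.028 with array weights, and ranged from -0.18 to 0.55 as arrays were left out. ERBB3 reversed to 0.10 with the mean of its probes. BIRC5 reversed to -0.0045 with chip as a block and ranged from -0.0045 to 1.15 as arrays were left out, and COL1A1 ranged from -0.98 to 0.48. The cause was not tested. Only 2 replicate numbers are shared and nothing in the labels says that they pair arrays. Deviations of arrays correlated between -0.0447 and 0.0447. With the replicate block the SETDB1 difference was -0.55, 0 genes were called and 6 lists passed. In the tally kept over the alternatives, 1423 values kept their direction and side of the threshold, 43 were no longer past it, 12 reversed and 16 counts moved by over 1.5 times. The tally does not hold the turns of the 17 lists that did not pass. No named gene was past the threshold, so a gene that changed only in size counts as kept. At most 46.1% of probes were above background on an array, which limits what dim genes can show.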

Other observations

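The 3 overexpression arrays differed among themselves in genes chosen here after their values were seen, as those of largest SD between them. The tryptophan-degrading enzyme KYNU read 4.69, 9.67 and 4.44 on overexpression replicates 1, 2 and 3, and 8.55 and 9.78 in the controls. The protease inhibitor PI3 read 4.69, 9.04 and 4.95, with 4.64 and 5.32 in the controls. The cytokine IL24 read 5.51, 8.42 and 5.18, with 5.08 and 5.51 in the controls. For PI3 and IL24 replicate 2 stood apart from the controls, while for KYNU replicates 1 and 3 did. The cancer-testis gene MAGEC1 read 4.47, 8.40 and 4.35, with 8.01 and 7.83 in the controls. In the other direction the phospholipase PLA1A read 11.95, 8.55 and 12.05, with 12.01 and 12.59 in the controls. TSPAN7 read 11.07, 7.50 and 11.10, with 10.37 and 10.21 in the controls.

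The cell cycle list had a median against the control mean of 0.64, -0.54 and 0.27 on the overexpression arrays, and 0.28 and -0.28 on the controls. The median SD per feature was 0.27 between the 3 overexpression arrays and 0.25 between the 2 controls. A median SD reads lower with fewer arrays, so these values do not show which group varied more.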
